A study of Zea mays with 18 samples.

How the data were processed

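Leaves of the maize hybrid Xianyu 335 were sampled at grain filling from 3 leaf positions at high and low plant density, and RNA was sequenced in 18 libraries, 3 in each of 6 groups. Per the labels, RNA was extracted with a Trizol-type reagent and libraries were made with an NEBNext Ultra RNA kit. The authors trimmed reads with Trimmomatic 0.35, aligned them to B73 RefGen_v3 with HISAT 0.1.6, counted them with HTSeq 0.6.1 and deposited RPKM values for 31855 gene models in each of 18 libraries. The RPKM formula, the gene lengths and the strandedness of the counts were not given in the sources used here, and raw reads were not used here.

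Groups were taken from the library titles: HA and LA for the third leaf above the ear, HE and LE for the ear leaf, and HB and LB for the third leaf below the ear, H standing for high and L for low density. The treatment label of the 3 LA libraries reads high plant density, against their titles, so every comparison with LA carries this conflict. The labels do not say that the 3 libraries of a group came from separate plants, so each p measures the spread between these samples. No batch, date or lane is given in the labels. A shared replicate number was checked as a pairing by correlating each library's deviation from its group mean with that of the library of the same number in each other group. In 2 of the 15 pairs of groups, HA with HE and HA with LB, all 3 correlations lay above 0.1. A fit with the replicate number as a block over all 18 libraries was given beside the unblocked one. It sets the same replicate effects for all 6 groups, although most pairs of groups showed no such pairing. It is therefore not a test of HA paired with HE.

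Gene names came from a RefSeq table of the assembly Zm-B73-REFERENCE-NAM-5.0, which matched 17838 gene models, 489 of them to more than 1 row, and gave 2317 a gene symbol. That assembly differs from the one the reads were aligned to, so names were used and positions were not. Pairs of gene models named rbcS or PGR5 share a RefSeq gene, and lists were matched by symbol without regard to case. Pep1 (GRMZM5G899080) is not the C4 enzyme gene pep1 (GRMZM2G083841) but joined the C4 shuttle and mesophyll lists through its name. Leaving it out left the number of called lists as it was in each of the 7 comparisons of 2 groups, and raised it from 3 to 4 for the lower-leaf interaction.

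The files gave no read counts. A relative depth was recovered from 4755 genes with very low values in few libraries, whose smallest RPKM stands for 1 read. Of 2916 values above 1 read, 99.6% lay within a tolerance of 0.1 of a whole multiple, against 20% of evenly spread values. The absolute depth stays unknown, so no counting intervals are given.

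Genes with at least 1 RPKM in at least 3 libraries were kept, and log2(RPKM + 0.5) was fitted with limma 3.58.1 in R 4.3.3, with a mean for each group and an intensity trend of the prior variance. Tests were 2-sided, with Benjamini-Hochberg adjustment over the genes tested in each comparison, and genes with adjusted p under 0.05 were called. The fit had 12 residual and 4.47 prior degrees of freedom. An exact permutation test of 3 against 3 libraries cannot give a p under 0.1. Interactions compared the density difference of the lower or upper leaf with that of the ear leaf. Gene lists were tested with limma's camera at a preset correlation of 0.01 where they had at least 5 tested members, adjusted over the lists of the comparison, and also with an estimated correlation. They were also tested with fry, which tests whether a list's genes move, on balance, in 1 direction without comparing them with other genes. Of 31 fixed lists of symbols, 9 were large enough to test. Because few symbols matched, 38 wider lists were built from patterns of gene names after the names in the files had been seen, and 35 of these were tested. The comparisons, tests, thresholds, fixed lists, rule for named genes and most alternatives were chosen before the data were examined.

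Named genes followed a rule. Among genes with a symbol, it took the 10 largest rises and 10 largest falls of each density comparison and 5 of each for position comparisons, with adjusted p under 0.05, a mean of at least 5 RPKM in the higher group and no overlap of the 3 and 3 libraries. It also took up to 2 called members of each list, the 5 largest called interactions, and phytochrome B, pep1 and Rubisco small subunit genes in each comparison, while 1 of the Rubisco genes sought, ssu2, was not identified. Density changes shared by the ear and lower leaves were measured by correlation across genes and by overlap of calls against the product of the shares. The genes called the same way in both were followed in the upper leaf against 10000 random gene sets matched on expression in 20 bins.

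The fit was tested on simulated data with each gene's residual spread over all 18 libraries, and with changes added to HE. Of 200 changed genes among 20729, 68% were called at a log2 change of 1 and 95% at 2. There were 13 unchanged genes called. In an unchanged comparison 1 gene was called and 5.09% of p lay under 0.05. Camera called 2 of 2 changed lists and 0 of 20 random lists. The noise was drawn for each gene from its own spread, without correlation between genes. The simulation therefore cannot check camera's preset correlation, on which the list calls below depend. The simulated spread of a gene was the same in all 6 groups, so the fit's assumption of equal spread was not checked either.

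Alternatives were pseudocounts of 0.1 and 1, no filter and a filter at 5 RPKM, median-ratio rescaling, quantile normalization, rescaling to a common sum, limma without the trend, the replicate number as a block, LA left out, only the libraries of the groups compared, a log2 change of at least 1, and each library left out in turn. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 prepared tables and figures.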

Results

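RNA sequencing measured transcript levels in leaves of the maize hybrid Xianyu 335 during grain filling. The third leaf above the ear (A), the ear leaf (E) and the third leaf below the ear (B) were sampled at high (H) and low (L) plant density, with 3 libraries in each of the groups HA, LA, HE, LE, HB and LB as titled. The treatment label of the LA libraries reads high plant density, which conflicts with their titles. Values were deposited as RPKM for 31855 gene models, of which 31234 lay above 0 in at least 1 library and 21184 passed the filter for testing. The sum of RPKM per library ranged from 560984 to 595593, and the 10 most abundant genes took 4.64% to 7.96% of it. Read totals were not given. The recovered relative depth ranged from 0.873 (HB replicate 1) to 1.10 (HA replicate 2), a ratio of 1.27. In rare genes 1 read stood for a median of 0.043 RPKM. The 6 LE and LB libraries had relative depths of 0.905 to 0.943 and 25749 to 26187 genes above 0, against 0.873 to 1.10 and 26271 to 27316 genes in the 12 others. Across genes, which are not independent replicates, HB libraries correlated at 0.970 to 0.976 within their group and at most at 0.948 with libraries of other groups. LB replicate 2 correlated at 0.954 to 0.957 with its own group and at up to 0.966 with an LE library. HA replicate 3 and LA replicate 1 correlated at 0.982 with each other and at most at 0.979 and 0.98 with their own groups. For every called gene named with values below, all 3 libraries of one group lay above or below all 3 of the other. The exception was gln3 in the ear leaf. The rule for the largest rises and falls required this of genes already called, so it adds no support. Among all tested genes it held for 13.9% (LB and LE) to 49% (HB and HE), where chance gives 10%.

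The ear leaf at high density was compared with the ear leaf at low density to ask which transcripts differ with crowding in the leaf that subtends the ear. dbf1 (GRMZM2G061487), an AP2 factor that binds dehydration-responsive promoter elements, rose from 11.96 ± 4.02 RPKM (mean ± SD, n = 3) in LE to 64.8 ± 52.1 in HE. TIP4-1 (GRMZM2G103945), a water channel of the vacuolar membrane, rose from 43.8 ± 14.6 to 131 ± 20.95 RPKM. lhcb5 (GRMZM2G149428), a minor antenna protein of photosystem II, rose from 209 ± 40.2 to 455 ± 35.3. CKX5 (GRMZM2G325612), an enzyme that degrades cytokinins, fell from 10.6 ± 3.17 to 0.443 ± 0.320 RPKM. fsd1 (GRMZM5G864424), an iron superoxide dismutase, fell from 30.5 ± 2.60 to 17.3 ± 2.92. The log2 fold changes of these genes were 2.12 ± 0.42 (SE), 1.60 ± 0.26, 1.14 ± 0.22, -3.56 ± 0.61 and -0.81 ± 0.14. Their limma adjusted p were 0.00614, 0.00209, 0.00554, 0.00267 and 0.00319.

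Among regulators in the ear leaf, the bZIP factors bZIP92 (GRMZM2G077124) and bZIP111 (GRMZM2G073427) rose by 1.75 and 1.64 on the log2 scale. PYL5 (GRMZM2G057959) of the abscisic acid receptor family rose by 1.302, WRKY29 (GRMZM2G040298) by 0.91 and the heat stress factor HSF6 (GRMZM2G059851) by 0.70. The vacuolar water channel TIP4-2 (GRMZM2G108273) rose by 0.93 and PPCK2 (GRMZM2G135091), a kinase of phosphoenolpyruvate carboxylase, by 0.92. The hypersensitive-induced reaction gene hir3 (GRMZM2G070659) rose from 375 ± 46.6 to 704 ± 9.50 RPKM. glossy2 (GRMZM2G098239), which acts in cuticular wax formation, rose by 0.80 on the log2 scale. The largest fall among genes named by the rule was that of kin1 (GRMZM2G158394), from 285 ± 47.4 to 19.98 ± 10.8 RPKM. The ribosomal protein gene rps10 (GRMZM2G095511) fell by 0.61. bk2 (GRMZM2G109326), a COBRA-like gene of secondary walls, fell by 1.69 at 1.54 RPKM or less. Of 64 called genes named by the rule in this comparison, 22 stayed called without any 1 library and 42 did not. limma adjusted p for the genes given above in this paragraph lay between 0.00165 and 0.00794, and each of these stayed called. The jasmonate repressor family member TIFY4 (GRMZM2G445634) had the largest rise among them, 3.70 ± 0.85 (adjusted p = 0.0112), but was not called without HE replicate 2 (adjusted p = 0.061). psy2 (GRMZM2G149317), the phytoene synthase of carotenoid formation, and dxs1 (GRMZM2G137151), the entry enzyme of plastid isoprenoids, fell by 1.18 and 1.44 (adjusted p = 0.029 and 0.0241). With 1 library left out, adjusted p for both reached 0.101. The psy2 call was lost without any library except HE replicate 1, and that of dxs1 without HE replicates 2 and 3 and LE replicates 1 and 3. The phytochrome B genes PHYB (GRMZM2G124532) and PhyB2 (GRMZM2G092174) had log2 fold changes of -0.02 (adjusted p = 0.96) and -0.43 (adjusted p = 0.0846). PhyB2 was called after median-ratio rescaling (-0.44), quantile normalization (-0.45) and with the replicate block. The C4 enzyme gene pep1 (GRMZM2G083841) and the Rubisco small subunit gene rbcS (GRMZM2G098520) were at -0.26 (adjusted p = 0.628) and 0.60 (adjusted p = 0.168), neither called.

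Among the fixed lists in the ear leaf, 2 of 7 members of the benzoxazinoid pathway, which makes defence compounds, were called higher, 3 when adjusted over the list alone. The glucosyltransferase gene bx9 (GRMZM2G161335) rose from 26.7 ± 2.85 to 45.0 ± 6.74 RPKM (adjusted p = 0.00443). Its relative bx8 (GRMZM2G085054) rose from 7.29 ± 0.04 to 12.6 ± 0.82 RPKM (adjusted p = 0.0239), a call lost without HE replicates 2 and 3 and LE replicates 1 and 3 (adjusted p up to 0.083). In nitrogen assimilation 2 of 8 members fell, the glutamine synthetase genes gln2 (GRMZM2G024104) and gln3 (GRMZM2G046601) at -1.76 and -1.24 (adjusted p = 0.0211 and 0.0266). Adjusted over the list alone, 1 member rose and 2 fell. The gln2 call was lost without any library except LE replicate 1 (adjusted p up to 0.0608), and that of gln3 without HE replicates 1 and 2 and LE replicates 1 and 2 (up to 0.13). The 6 photosystem and electron transport genes and 8 C4 shuttle genes held 0 called members, also adjusted over the list alone, with median log2 fold changes of 0.25 and -0.08. limma's camera called 0 of the 9 fixed lists, with the benzoxazinoid pathway lowest at adjusted p = 0.529, and fry called 0. Among the wider lists, 7 of 17 AP2/ERF factors rose and 0 fell (median 0.48, camera adjusted p = 0.0379; adjusted p = 0.811 with an estimated correlation). Of 18 antioxidant enzymes, 6 fell and 1 rose (median -0.21, camera adjusted p = 0.0178; adjusted p = 0.811 with an estimated correlation). Of 22 genes of plastid pigments and isoprenoids 5 fell (median -0.29, camera adjusted p = 0.0379; adjusted p = 0.811 with an estimated correlation). Of 30 ribosomal proteins 2 fell (median -0.16, camera adjusted p = 0.0178; adjusted p = 0.811 with an estimated correlation). Quantile normalization ended all 4 calls (adjusted p = 0.0883 for AP2/ERF factors, 0.136 for pigments and 0.12 for the other 2), and median-ratio rescaling ended that of pigments (0.0834). The AP2/ERF call was also lost without HE replicate 3 (0.0684), LE replicate 1 (0.0508) or LE replicate 3 (0.0754). The pigment call was lost without LE replicate 1 (0.0508) and the ribosomal call without LE replicate 3 (0.0731). Called members fell without HE replicate 2 to 2 AP2/ERF factors, 1 lower antioxidant gene and 0 pigment genes. Without LE replicate 1 they fell to 2, 2 and 0, and without HE replicate 3 or LE replicate 3 to 4, 2 and 0. Without LE replicate 2 they were 4 AP2/ERF factors and 2 pigment genes.

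In all, limma called 2953 of 21184 genes between HE and LE, 1900 higher and 1053 lower in HE, of which 768 and 152 had an absolute log2 fold change of at least 1. The libraries of both groups did not overlap for 40.9% of genes. After quantile normalization 3059 genes were called, 1414 higher and 1645 lower, so the share higher was 46.2% instead of 64.3%. The count fell to 901 without HE replicate 2, 1275 without HE replicate 3, 1065 without LE replicate 1 and 1442 without LE replicate 3. It rose to 4168 with only the HE and LE libraries in the fit.

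The third leaf below the ear at high density was compared with the same leaf at low density to ask how crowding goes with the lower leaves, the first to age. ICL (GRMZM2G056369) and LIP (GRMZM2G102183), the isocitrate lyase and malate synthase of the glyoxylate cycle that turns lipid carbon into sugar precursors, rose from 0.224 ± 0.210 and 0.246 ± 0.241 RPKM in LB to 202 ± 136 and 134 ± 63.2 in HB (n = 3). SGR2 (GRMZM2G091837), a stay-green protein that starts chlorophyll breakdown, rose from 6.09 ± 1.74 to 46.4 ± 14.2 RPKM. The C4 phosphoenolpyruvate carboxylase gene pep1 fell from 3736 ± 1606 to 484 ± 124 RPKM, and SPS (GRMZM5G875238), the sucrose-phosphate synthase, fell from 243 ± 23.6 to 63.6 ± 10.7. On the scale of log2(RPKM + 0.5), where the pseudocount limits folds against values near 0, these changes were 7.91 ± 0.38 (SE), 7.43 ± 0.28, 2.83 ± 0.28, -2.88 ± 0.32 and -1.94 ± 0.15. Their limma adjusted p were 3.31e-09, 1.23e-10, 9.44e-06, 2.53e-05 and 7.74e-07. The plot of 8 genes in the 18 libraries shows these levels.

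**Figure D1:**
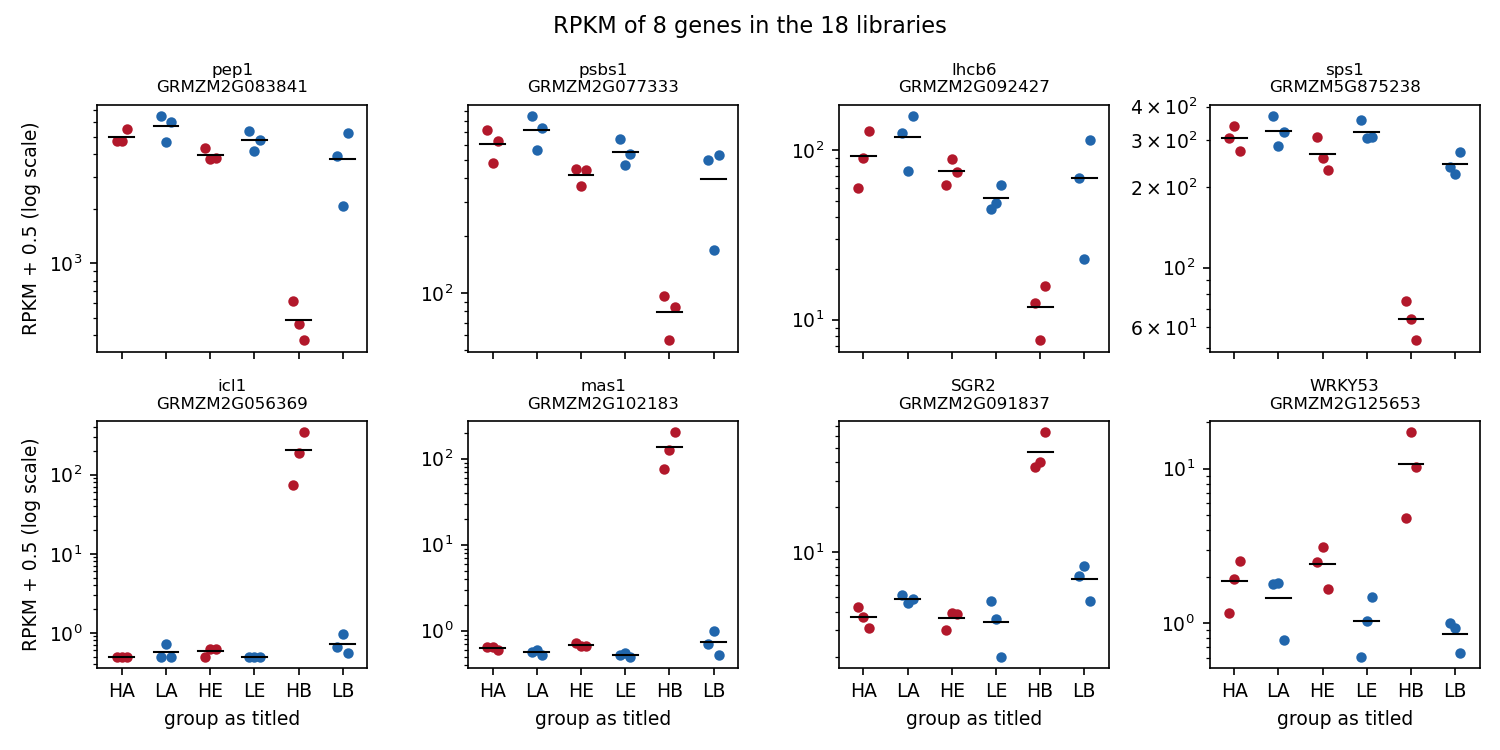
RPKM + 0.5 on a log scale of 8 genes in each of the 18 libraries (points, red for titles of high and blue for titles of low density), with the mean of each group as a line; icl1, mas1, psbs1, lhcb6, sps1 and WRKY53 are the genes named ICL, LIP, CP22, CP24, SPS and WRKY in the text. The 3 HB libraries of ICL average 202 RPKM against 0.224 in LB, and those of pep1 484 against 3736.

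All 6 tested members of the fixed list of photosystem cores and electron transport fell in HB (6 adjusted over the list alone). Their median log2 fold change was -1.32 (camera adjusted p = 3.95e-05; adjusted p = 0.145 with an estimated correlation). Among them CP22 (GRMZM2G077333), the PsbS protein of photoprotection, fell from 397 ± 199 to 78.7 ± 20.5 RPKM. FdI (GRMZM2G122337), a leaf ferredoxin, fell by 2.06 on the log2 scale. All 3 antenna genes fell (3 adjusted over the list alone; median -2.01). CP24 (GRMZM2G092427) fell from 68.04 ± 46.0 to 11.4 ± 4.16 RPKM and cab-m9 (GRMZM2G155216) from 107 ± 68.2 to 25.04 ± 11.6. All 4 Calvin cycle genes fell (4 adjusted over the list alone; median -1.34). The chloroplast glyceraldehyde-3-phosphate dehydrogenase subunit gene G3PD (GRMZM2G337113) fell from 1235 ± 527 to 372 ± 80.0 RPKM, and its partner gpb1 (GRMZM5G845611) fell from 737 ± 403 to 155 ± 41.6. Lists of under 5 members were not tested as lists. ChlI (GRMZM2G419806), a magnesium chelatase subunit of chlorophyll synthesis, fell by 1.18. Of 8 C4 shuttle members 4 fell and 1 rose (4 and 1 adjusted over the list alone), with a median of -0.51 (camera adjusted p = 0.0133; adjusted p = 0.145 with an estimated correlation). The member that rose, Pep1 (GRMZM5G899080), joined by its name and is not the C4 enzyme. Without it 7 members had a median of -0.69 (camera adjusted p = 0.00113; adjusted p = 0.116 with an estimated correlation). The call of 8 was lost after median-ratio rescaling (0.0632) and quantile normalization (0.088). Of 7 benzoxazinoid genes 5 fell and 1 rose (5 and 1 adjusted over the list alone), with a median of -0.86 (camera adjusted p = 0.00782; adjusted p = 0.145 with an estimated correlation). Without HB replicate 3, LB replicate 1 or LB replicate 3, 3 of the 7 were called lower. The cytochrome P450 genes BX3 (GRMZM2G167549) and BX4 (GRMZM2G172491) of this pathway fell by 1.90 and 1.70. Markers of both photosynthetic cell types moved with these genes. Of 6 mesophyll markers, pep1 among them, 3 fell and 1, Pep1 again, rose (3 and 1 adjusted over the list alone). Their median was -0.73 (camera adjusted p = 0.0458, and adjusted p = 0.158 with an estimated correlation). Without Pep1 the 5 other mesophyll markers had a median of -1.394 (camera adjusted p = 0.0032, and adjusted p = 0.116 with an estimated correlation). All 3 bundle sheath markers fell (3 adjusted over the list alone; median -0.69), but the call of ME1 (GRMZM2G085019), the NADP-malic enzyme, was lost without any library except HB replicate 1 (adjusted p up to 0.148). The mesophyll call of 6, with Pep1, was lost after median-ratio rescaling (0.129) and quantile normalization (0.088). It was also lost without HB replicate 1 (0.0624), HB replicate 2 (0.0664), LB replicate 2 (0.0667) or LB replicate 3 (0.0714). The Rubisco small subunit gene models rbcS (GRMZM2G098520 and GRMZM2G113033), bundle sheath genes, fell by 1.02 and 1.11 (adjusted p = 0.0125 and 0.00955). The first was lost without HB replicate 2 or LB replicate 3 (adjusted p up to 0.0656) and the second without LB replicate 3 (adjusted p = 0.0537).

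The wider lists in the lower leaf showed 15 of 19 photosystem and electron transport genes lower and 2 higher in HB (median -0.92, camera adjusted p = 2.76e-08; adjusted p = 0.332 with an estimated correlation). There were 5 of 7 antenna genes lower (median -1.21, adjusted p = 0.00199; adjusted p = 0.362 with an estimated correlation). Of the Calvin cycle and Rubisco assembly, 6 of 8 genes were lower (median -0.96, adjusted p = 0.000169; adjusted p = 0.333 with an estimated correlation). Of 17 WRKY factors 13 rose and 0 fell (median 0.72, adjusted p = 0.00155; adjusted p = 0.333 with an estimated correlation). After median-ratio rescaling 9 of the 17 were called higher, and without HB replicate 3 it was 8. The Calvin cycle list held 3 lower genes without HB replicate 2 and 2 without LB replicate 3. WRKY (GRMZM2G125653) rose from 0.359 ± 0.189 to 10.2 ± 6.19 RPKM and WRKY104 (GRMZM2G169149) from 0.177 ± 0.212 to 7.96 ± 5.52. These 4 lists stayed called under each of 3 scalings, the replicate block and without any 1 library. Of 22 genes of senescence and autophagy 11 rose and 1 fell (median 0.38, adjusted p = 0.0276; adjusted p = 0.527 with an estimated correlation), lost without HB replicate 3 (0.0623). After median-ratio rescaling 7 rose and 1 fell (median 0.25), and 5 rose without LB replicate 1 and 6 without HB replicate 3 or LB replicate 3. Of 18 antioxidant enzymes 7 were lower and 3 higher (median -0.21, adjusted p = 0.00517; adjusted p = 0.333 with an estimated correlation). Of 22 plastid pigment genes 10 were lower and 6 higher (median -0.34, adjusted p = 0.00471; adjusted p = 0.333 with an estimated correlation). Both calls were lost after quantile normalization (0.104 and 0.0798), and after median-ratio rescaling 0 antioxidant and 3 pigment genes were higher. Higher antioxidant genes were 1 without HB replicate 2 and 0 without HB replicate 3 or LB replicate 3, and higher pigment genes 2 without HB replicate 3. The nitrogen list of 17 had 6 members lower and 2 higher, with a median of 0.04, a mean of -0.14 and a test toward lower (adjusted p = 0.0354; adjusted p = 0.332 with an estimated correlation). The call was lost after each of 3 scalings (0.0551, 0.207 and 0.0555) and without LB replicate 1 (0.053) or LB replicate 3 (0.06), and the median was -0.08 after median-ratio rescaling, -0.217 after quantile normalization and -0.08 without LB replicate 1. After median-ratio rescaling and without HB replicates 2 or 3 or LB replicates 1 or 3, 1 member was higher. The other 5 of the 13 called wider lists were the C4 shuttle, sucrose and starch, benzoxazinoid, ribosomal and bundle sheath lists, all toward lower. Their camera adjusted p lay between 0.0105 and 0.0408 (adjusted p = 0.332 to 0.646 with an estimated correlation). Each of these 5 was lost after quantile normalization, and the C4, sucrose and starch, and bundle sheath lists also after median-ratio rescaling (0.0564, 0.081 and 0.0888). Leaving out HB replicate 2 ended the wider C4 call (0.0517), LB replicate 1 that of ribosomal proteins (0.156), and HB replicate 1 (0.0674) or LB replicate 1 (0.075) that of sucrose and starch. Leaving out HB replicate 2 (0.11), HB replicate 3 (0.0518), LB replicate 1 (0.0619) or LB replicate 3 (0.108) ended that of the bundle sheath.

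Single genes in the lower leaf that rose included GH3 (GRMZM2G378106), of the family that conjugates auxin, by 2.82 on the log2 scale, and the AP2 factors EREB92 (GRMZM2G174347) and dbf1 by 2.27 and 2.04. acco20 (GRMZM2G126732), an enzyme of ethylene synthesis, rose by 2.07 and the calcium sensor gene CBL10 (GRMZM2G116584) by 3.47. The sucrose synthase gene SH-1 (GRMZM2G089713) rose from 51.9 ± 26.8 to 147 ± 11.6 RPKM, and Agp2 (GRMZM2G106213), of ADP-glucose formation for starch, by 1.83. The homeobox gene gt1 (GRMZM2G005624) rose by 1.72 and the transcription factor NAC75 (GRMZM2G100583) from 90.8 ± 12.2 to 191 ± 19.2 RPKM. Those that fell included AAMT2 (GRMZM2G116966), an anthranilate methyltransferase, by 2.90, and the FT-like genes ZCN7 (GRMZM2G141756) and ZCN8 (GRMZM2G179264) by 2.50 and 2.33. PGR5 (GRMZM2G121494) of cyclic electron flow fell by 2.14 and mdh6 (GRMZM2G129513), the C4 malate dehydrogenase, from 958 ± 210 to 331 ± 34.1 RPKM. Falls were also seen in gln3 by 1.77, fsd1 by 1.28 and kin1 by 4.67. limma adjusted p for these genes lay between 6.88e-06 and 0.00652, and each stayed called without any 1 library. PHYB and PhyB2 had log2 fold changes of 0.05 and -0.14 (adjusted p = 0.88 and 0.534). In all, limma called 7070 genes, 4676 higher and 2394 lower in HB, of which 1459 and 710 had an absolute log2 fold change of at least 1, and libraries did not overlap for 39.9% of genes. The median log2 fold change of all genes was 0.16, against 0.03 after median-ratio rescaling and -0.01 after quantile normalization. The called genes were then split 3229 higher to 3202 lower and 2991 to 3539, 50.2% and 45.8% higher instead of 66.1%, while the 6 fixed photosystem genes had a median of -1.45 and -1.26. Without LB replicate 3 the count was 4601, and without LB replicate 2, the library apart from its group, 8973. With only the HB and LB libraries in the fit it was 4264, and HE against LE fitted alone gave 4168. That the lower leaf had the larger count, 7070 against 2953, thus depends largely on the spread shared by all 6 groups.

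**Figure D2:**
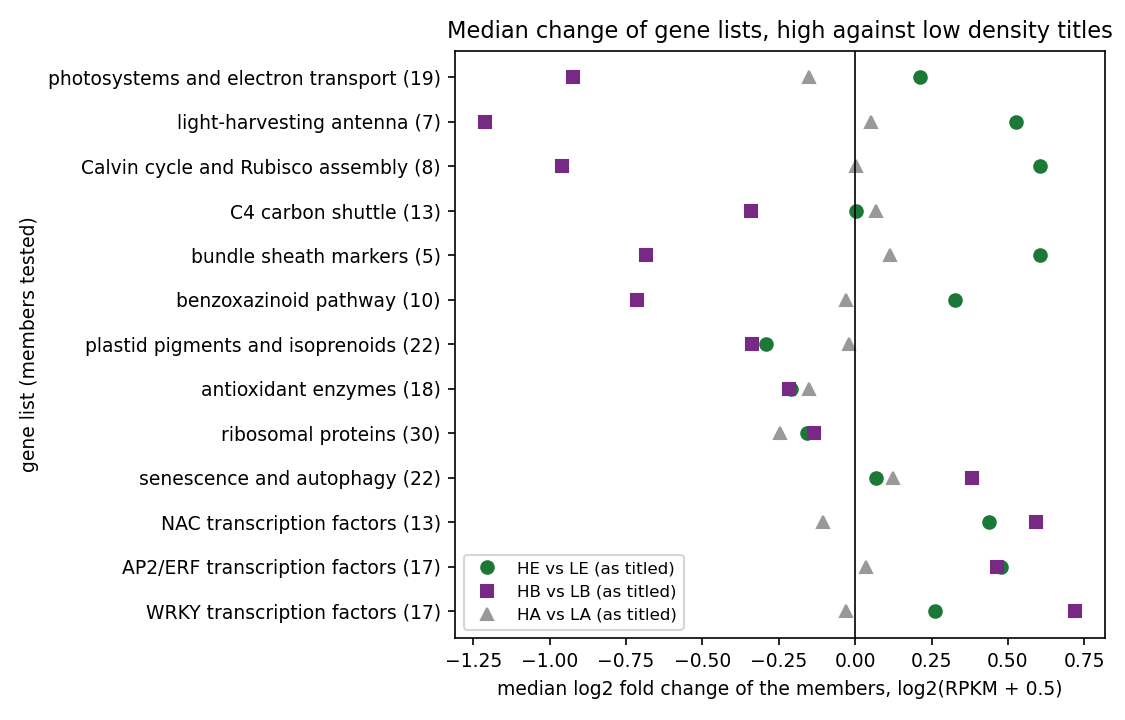
Median log2 fold change of the members of 13 wider gene lists (members tested in brackets) for HE against LE (circles), HB against LB (squares) and HA against LA (triangles), groups as titled and the treatment label of LA reading high density. The photosystem, antenna and Calvin cycle lists lie at -0.92, -1.21 and -0.96 in the lower leaf, and at 0.21, 0.53 and 0.60 in the ear leaf, where camera called none of the 3.

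Whether density went with the same genes in the ear and lower leaves was asked across all tested genes. dbf1 rose in both leaves (2.12 and 2.04), acco20 in both (1.57 and 2.07), and fsd1 (-0.81 and -1.28), kin1 (-3.97 and -4.67), psy2 (-1.18 and -1.94) and dxs1 (-1.44 and -2.18) fell in both; the ear leaf call of acco20 was lost without HE replicate 2 or LE replicate 1 (adjusted p up to 0.0616). Calls overlapped at 1141 genes higher in both and 589 lower in both, against 419 and 119 from the product of the shares, and 41 genes were called in opposite directions. The log2 fold changes of the ear and lower leaf, which share no library, correlated across 21184 genes at Pearson's r = 0.576 and Spearman's rho = 0.572, and 68.7% of genes had the same sign. Genes are not independent replicates. Both sets of calls used the same fitted spread of each gene, so genes of low spread are called more readily in both. The product of the shares is therefore not a chance level of the overlap. The 6 LE and LB libraries are the low-density side of both changes. They had 25749 to 26187 genes above 0, against 26271 to 27316 in the 12 others. How far this library difference adds to the shared changes was not tested.

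**Figure D3:**
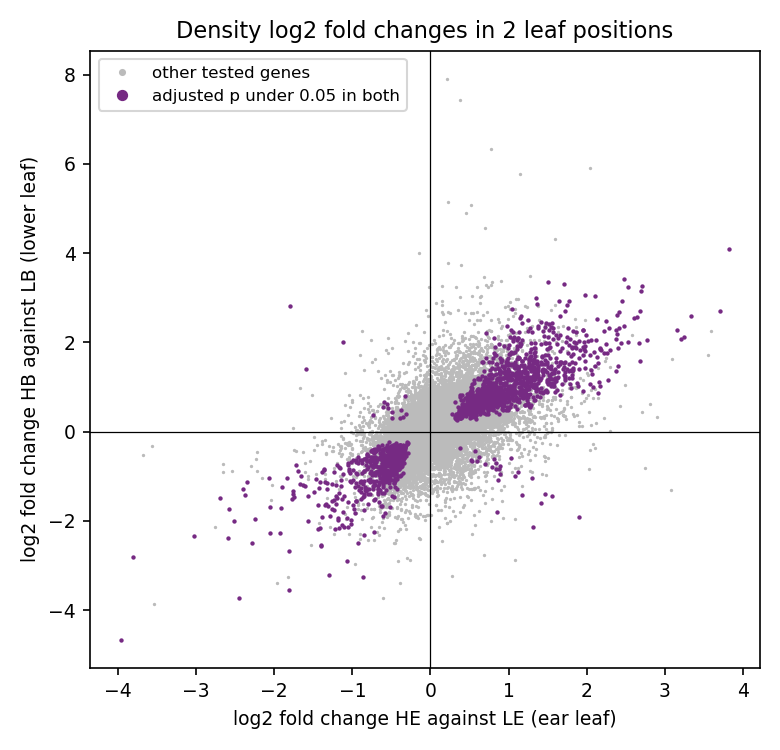
Log2 fold change of each tested gene in HE against LE (x axis) and in HB against LB (y axis), with genes called in both in purple. The called genes lie mostly in the quadrants of equal sign, 1141 higher in both and 589 lower in both, with 41 of opposite sign.

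The difference between both density changes, that of the lower leaf minus that of the ear leaf, was tested as an interaction. Among genes with a symbol ICL and LIP differed most, by 7.70 ± 0.54 and 7.06 ± 0.40 (SE) on the log2 scale (adjusted p = 1.14e-06 and 7.1e-08). GH3 fell in the ear leaf by 1.79 and rose in the lower leaf by 2.82, an interaction of 4.61 ± 0.70 (adjusted p = 0.00323). The fall in the ear leaf was lost when any library except LE replicate 3 was left out (adjusted p up to 0.0983). pep1 had an interaction of -2.61 ± 0.46 (adjusted p = 0.00728) and RADIALIS (GRMZM2G114503), a MYB-like factor, of -3.44 ± 0.36 (adjusted p = 9.04e-05). These 5 stayed called without any 1 library. CKX5 had an interaction of 3.24 ± 0.86 (adjusted p = 0.0457). It was lost in 10 of the 12 fits that left out a library (0.139 without LB replicate 3) and after median-ratio rescaling. rbcS had an interaction of -1.62 ± 0.41 (adjusted p = 0.0364), likewise lost after median-ratio rescaling and in 10 of 12 (0.109 without LB replicate 3). Among fixed lists, 3 of 6 photosystem genes had a called interaction toward lower in HB (6 adjusted over the list alone; median -1.67, camera adjusted p = 4.16e-07, and adjusted p = 0.091 with an estimated correlation). The called members were 0 of 6 after median-ratio rescaling and 0 without any 1 library except HB replicate 1 (5) and LB replicate 2 (6), and 6 with the replicate block, while camera called the list each time. So did 4 of 7 benzoxazinoid genes (4 adjusted over the list alone; median -1.296, adjusted p = 1.42e-06, and adjusted p = 0.0544 with an estimated correlation), or 2 of 7 without HE replicates 2 or 3, HB replicate 3, LE replicates 1 or 3 or LB replicates 1 or 3. In the C4 list it was 1 of 8 genes (4 adjusted over the list alone; median -0.65, adjusted p = 0.012, and adjusted p = 0.106 with an estimated correlation). The C4 call was lost after median-ratio rescaling (0.0569) and quantile normalization (0.0848), and its called members were 2 after quantile normalization, with the replicate block or without HB replicate 1, and 3 without LB replicate 2. Without Pep1 the 7 C4 members had a median of -0.955 (camera adjusted p = 0.00128; adjusted p = 0.0663 with an estimated correlation). The 5 mesophyll markers, not called with it, then had a camera adjusted p of 0.0104 (adjusted p = 0.155 with an estimated correlation). Camera called 10 wider lists, 8 toward lower and 2 toward higher. Among them, 5 of 7 antenna genes and 5 of 8 Calvin cycle genes had interactions toward lower (medians -2.20 and -1.68, adjusted p = 2.62e-07 and 1.58e-07; adjusted p = 0.124 with an estimated correlation for both). These were 3 of 7 and 2 of 8 after median-ratio rescaling, 0 and 0 without LB replicate 3, and 0 to 3 without any 1 other library except HB replicate 1, HB replicate 3 for the antenna, and LB replicate 2. Markers of another cell type moved the same way: 3 of 5 bundle sheath markers, all members of the C4 or Calvin cycle lists, had interactions toward lower (median -1.24, adjusted p = 3.39e-05; adjusted p = 0.127 with an estimated correlation). This list stayed called by camera under each of 3 scalings, the replicate block and without any 1 library, but its called members were 1 after median-ratio rescaling and 0 or 1 without any 1 library except HB replicate 1 and LB replicate 2. Of 11 cuticle and epidermis markers 1 was lower (median -0.299, adjusted p = 0.0022; adjusted p = 0.124 with an estimated correlation). The lists toward higher were senescence and autophagy and the WRKY factors. Of 22 senescence genes 4 were higher (median 0.293, adjusted p = 0.00483; adjusted p = 0.447 with an estimated correlation), or 2 without HE replicates 2 or 3, HB replicate 2, LE replicate 2 or LB replicate 3 and 7 without LB replicate 2, with the list called each time. Of 17 WRKY factors 1 was higher (median 0.362, adjusted p = 0.0343; adjusted p = 0.664 with an estimated correlation), and 0 were after median-ratio rescaling and in 10 of the 12 fits without 1 library. The WRKY call was lost without HE replicate 1 (0.0651), HB replicates 2 (0.0732) or 3 (0.0655), LE replicate 2 (0.173) or LB replicates 1 (0.0508) or 2 (0.101). In all, 815 genes had a called interaction, 372 higher and 443 lower. The split turned to 1732 higher and 1201 lower without LB replicate 2, the library apart from its group, to 175 and 140 without HB replicate 2, and to 295 and 264 without a filter. It was near even without HE replicate 1 (163 and 159), HE replicate 3 (142 and 141), LB replicate 1 (168 and 166) and LB replicate 3 (111 and 110). The count was 322, 348 and 283 without HE replicates 1, 2 and 3 and 518, 266 and 460 without LE replicates 1, 2 and 3. It was 315 and 440 without HB replicates 2 and 3, and 334, 2933 and 221 without LB replicates 1, 2 and 3.

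The third leaf above the ear titled high density (HA) was compared with that titled low density (LA), whose treatment label reads high density, so a density effect cannot be read from it. MYBR47 (GRMZM2G117497), a MYB-related factor, was higher in HA at 14.2 ± 5.80 RPKM against 0.880 ± 0.295 in LA, 3.35 ± 0.36 (SE) on the log2 scale (adjusted p = 0.00103), and stayed called without any 1 library. MYBR87 (GRMZM2G158117) rose from 8.38 ± 2.46 to 46.0 ± 17.4 RPKM (adjusted p = 0.0117), and ARGOS7 (GRMZM2G113583), of a family that acts in organ size, fell from 13.3 ± 1.84 to 4.44 ± 1.81 (adjusted p = 0.0137). Both were lost without HA replicate 3, LA replicate 1 or LA replicate 2 (adjusted p up to 0.0679 and 0.101). D53 (GRMZM2G109674), a repressor of strigolactone signalling, was higher by 1.13 (adjusted p = 0.0482) and lost without any 1 of the 6 libraries (up to 0.229) and with a pseudocount of 0.1. pep1, rbcS, PHYB and PhyB2 had log2 fold changes of -0.19, -0.02, 0.08 and -0.04 (adjusted p from 0.89 to 0.992). Camera and fry each called 0 of 9 fixed lists. Of the 35 wider lists tested camera called 7, among them 30 ribosomal proteins lower (median -0.25, adjusted p = 8.81e-13; adjusted p = 0.246 with an estimated correlation) and 18 antioxidant enzymes lower (median -0.15, adjusted p = 0.000287; adjusted p = 0.279 with an estimated correlation), each with 0 called members. The 7 became 3 after quantile normalization and 4 without LA replicate 1, and fry called 0. In all, limma called 25 genes, 12 higher and 13 lower, with 1864 at an unadjusted p under 0.05. There was no overlap for 14.3% of genes. The count was 8 without HA replicate 2, 3 without HA replicate 3, and 2, 4 and 16 without LA replicates 1, 2 and 3. The interaction with the ear leaf had 0 called genes in limma and 3284 at an unadjusted p under 0.05, and 12 called genes with the replicate number as a block. There were 31 called without HE replicate 1, 18 without HA replicate 2 and 11 without LA replicate 3. Camera called 4 wider lists lower in this interaction, each with 0 called members and an adjusted p of 0.747 with an estimated correlation, and fry called 0. They were the WRKY factors (median -0.344, adjusted p = 0.0136), AP2/ERF factors, NAC factors and glutathione S-transferases (medians -0.471, -0.442 and -0.344, adjusted p = 0.0361 for each). Of these the WRKY call alone stayed under each of 3 scalings and without any 1 library. That of AP2/ERF factors was lost without HA replicate 2 (0.0698) or LE replicate 3 (0.0709), and that of NAC factors without LE replicate 3 (0.0585) and after rescaling to a common sum (0.113). The glutathione S-transferases were lost after median-ratio rescaling (0.0868) and without HA replicate 2 (0.0731), HE replicate 3 (0.125) or LE replicate 3 (0.0773). The 1730 genes called the same way in the ear and lower leaves had a median difference of 0.16 between HA and LA in that direction, against 0.78 and 0.87 in the ear and lower leaves themselves. Of these genes 74.8% had the same sign in HA against LA, and 0 of 10000 matched random sets reached their median (random medians 0.01 to 0.04), but another split of the 6 libraries reached 0.26.

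The upper leaf was compared with the ear leaf at high density. CKX5 was higher in HA at 55.5 ± 24.1 RPKM against 0.443 ± 0.320 in HE, 5.84 ± 0.61 (SE) on the log2 scale (adjusted p = 7.09e-05). crr1 (GRMZM2G040736), a cytokinin response regulator, was higher at 71.8 ± 16.2 against 7.60 ± 2.90 RPKM (adjusted p = 0.00258). The carotene hydroxylase genes BCH1 (GRMZM2G164318) and BCH2 (GRMZM2G152135) were higher by 2.72 and 2.13 (adjusted p = 0.000201 and 0.00332), GH3 by 3.21 and the nitrate reductase gene NNR1 (GRMZM2G568636) by 0.97. The chalcone synthase gene whp (GRMZM2G151227), of flavonoid synthesis, was higher by 4.02. The MADS-box genes m20 (GRMZM2G059102) and m5 (GRMZM2G171365) were lower. m20 stood at 6.50 ± 1.03 against 38.8 ± 2.74 RPKM (log2 fold change -2.50, adjusted p = 6.22e-05), and m5 had a log2 fold change of -2.14 (adjusted p = 7.62e-06). All these genes stayed called without any 1 library. Of 25 cytokinin genes 7 were higher and 0 lower (median 0.09, mean 0.67, camera adjusted p = 0.000453; adjusted p = 0.488 with an estimated correlation), and of 22 plastid pigment genes 4 were higher (median 0.17, adjusted p = 0.00239; adjusted p = 0.903 with an estimated correlation). The only wider list called lower was that of 5 bundle sheath markers, with 0 called members (median -0.685, adjusted p = 0.0211; adjusted p = 0.916 with an estimated correlation). It was lost after median-ratio rescaling (0.0557) and without HA replicate 1 (0.202) or HE replicate 3 (0.0704). Camera and fry called 0 of 9 fixed lists. limma called 516 genes, 252 higher and 264 lower, and 871 with the replicate number as a block; the libraries did not overlap for 23.4% of genes. The count was 193, 818 and 158 without HA replicates 1, 2 and 3, and 229 and 236 without HE replicates 2 and 3. The split turned to 266 higher and 241 lower after median-ratio rescaling and 316 and 286 after quantile normalization. Other settings that turned it were no filter (224 and 194), an absolute log2 fold change of at least 1 (172 and 148), limma without trend (261 and 250) and a pseudocount of 1 (252 and 250). It was 118 and 75 without HA replicate 1, 93 and 65 without HA replicate 3, 128 and 101 without HE replicate 2, and 142 and 94 without HE replicate 3.

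The lower leaf was compared with the ear leaf at high density. ICL and LIP were higher in HB by 8.19 and 7.51 on the log2 scale, and SGR2 at 46.4 ± 14.2 against 3.11 RPKM (log2 fold change 3.67, adjusted p = 6.55e-07). MPI (GRMZM2G028393), a proteinase inhibitor, was higher at 637 ± 137 against 84.4 ± 48.5 RPKM (adjusted p = 0.0028). pep1 was lower at 484 ± 124 against 3969 ± 289 RPKM (-3.06, adjusted p = 1.26e-05). So was C4ppdkZm1 (GRMZM2G306345), the pyruvate phosphate dikinase of the C4 cycle, at 1849 ± 390 against 5141 ± 672 (adjusted p = 0.00166). The MADS-box gene m15 (GRMZM2G553379) at 0.893 ± 0.085 against 26.7 ± 9.66 RPKM and RADIALIS at 7.37 ± 1.63 against 125 ± 5.65 were lower, with log2 fold changes of -4.23 and -4.01. All these genes stayed called without any 1 library. All 6 fixed photosystem genes were lower (6 adjusted over the list alone; median -1.38, camera adjusted p = 3.77e-05), as were 4 of 8 C4 genes (4 adjusted over the list alone; median -0.49, adjusted p = 0.00981), both at adjusted p = 0.151 with an estimated correlation. Of 7 benzoxazinoid genes 4 were lower and 1 higher (4 and 1 adjusted over the list alone; median -1.05, adjusted p = 0.00852), and 3 of 6 mesophyll markers were lower (3 adjusted over the list alone; median -0.67, adjusted p = 0.027). Both had adjusted p = 0.151 with an estimated correlation. The mesophyll call of 6, Pep1 among them, was lost after median-ratio rescaling (0.0867) and without HE replicate 1 (0.0601) or HB replicate 2 (0.066). Without Pep1 the 5 other mesophyll markers had a median of -1.288 (camera adjusted p = 0.00437, and adjusted p = 0.148 with an estimated correlation). In the wider list, 3 of 5 bundle sheath markers were lower too (median -0.776, adjusted p = 0.0239; adjusted p = 0.49 with an estimated correlation). That call was lost after median-ratio rescaling (0.0598), quantile normalization (0.123) and without HB replicate 2 (0.0649). Of the wider lists, 10 of 22 senescence and autophagy genes were higher (median 0.37, adjusted p = 0.00115; adjusted p = 0.489 with an estimated correlation) and 10 of 17 WRKY factors (median 0.47, adjusted p = 0.0067; adjusted p = 0.489 with an estimated correlation), the latter 6 without any 1 library except HB replicate 1. limma called 5904 genes, 3647 higher and 2257 lower, with no overlap for 49% of genes and a median of all genes of 0.11. The share higher was 47.5% of 5407 genes after median-ratio rescaling and 49.5% of 5923 after quantile normalization, against 61.8%.

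The leaf titled LA, with the label conflict, was compared with the ear leaf at low density. NNR1 was higher at 52.9 ± 2.11 against 21.7 ± 3.38 RPKM (adjusted p = 0.00217), and zap1 (GRMZM2G148693), a MADS-box gene, at 13.2 ± 4.25 against 3.60 ± 0.69 (adjusted p = 0.00655). m20 was lower at 6.23 ± 2.93 against 27.96 ± 4.74 RPKM (log2 fold change -2.19, adjusted p = 0.00162) and m5 by a log2 fold change of -1.67. bx8 was higher by 1.15 (adjusted p = 0.00927), and 3 of 7 benzoxazinoid genes were higher (4 adjusted over the list alone; median 0.53, camera adjusted p = 0.00181, and adjusted p = 0.292 with an estimated correlation), the only fixed list called of 9. These genes and this list stayed called without any 1 library, but 1 of its members was called without LA replicate 1, LE replicate 1 or LE replicate 3. Camera called 10 wider lists, all higher, each at adjusted p = 0.515 with an estimated correlation, and fry called 0. The 10 became 5 without LA replicate 2, 5 without LE replicate 1 and 1 without LE replicate 3. Of 19 photosystem genes 2 were higher (median 0.26, adjusted p = 0.00467), and 1 without LA replicates 1 or 3 or LE replicates 1 or 3. Of 11 cuticle and epidermis markers 1 was higher (median 0.388, adjusted p = 0.0317), and 4 with the replicate block. This call was lost without LA replicate 3 (0.0627), LE replicate 1 (0.0581) or LE replicate 3 (0.0649). limma called 1215 genes, 768 higher and 447 lower, with no overlap for 32.8% of genes. The share higher of 63.2% became 73.8% of 1513 genes after median-ratio rescaling, 46.5% of 1438 after rescaling to a common sum and 50.3% of 2320 with the replicate block. Without LA replicate 2 the excess turned, with 343 of 817 called genes higher and 474 lower. The count was 128 without LA replicate 1 and 111, 465 and 460 without LE replicates 1, 2 and 3.

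The lower leaf was compared with the ear leaf at low density. The MADS-box genes m4 (GRMZM2G032339) and m15 were lower in LB. m4 stood at 2.09 ± 0.82 against 67.3 ± 18.2 RPKM (log2 fold change -4.72 ± 0.30 (SE), adjusted p = 2.2e-07), and m15 at 0.650 against 27.6 ± 10.4 (adjusted p = 2.51e-08). ZIP4 (GRMZM2G111300), of the zinc transporter family, was higher at 37.6 ± 7.07 against 13.3 ± 3.39 RPKM (adjusted p = 0.00102). These 3 stayed called without any 1 library. ZCN8, lower by a log2 fold change of -1.60 (adjusted p = 0.0286), was lost without LE replicates 1 or 3 or LB replicates 2 or 3 (up to 0.166) and after median-ratio rescaling. Camera called the benzoxazinoid list of 7 higher with 0 called members (1 adjusted over the list alone; median 0.28, adjusted p = 0.0299, and adjusted p = 0.392 with an estimated correlation). It was lost after median-ratio rescaling (0.0608) and without LE replicates 2 (0.0705) or 3 (0.0742) or LB replicates 1 (0.157) or 3 (0.0594). Of the wider lists camera called 4, all higher, and fry 0. The 4 became 2 after median-ratio rescaling, 7 with the replicate block, 2 without LE replicates 2 or 3 or LB replicate 3, and 11 without LB replicate 2. Among them 5 bundle sheath markers had 0 called members (median 0.443, adjusted p = 0.013; adjusted p = 0.8 with an estimated correlation). That call was lost after median-ratio rescaling (0.0549) and without LE replicates 2 (0.0667) or 3 (0.0971) or LB replicates 1 (0.0585) or 3 (0.144). limma called 61 genes, 46 higher and 15 lower, with 2552 at an unadjusted p under 0.05. There was no overlap for 13.9% of genes. The share higher of 75.4% became 87.8% of 49 genes after median-ratio rescaling and 56.4% of 195 with the replicate block. The count was 30 and 23 without LE replicates 1 and 3 and 34 without LB replicate 3.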

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

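Of the tests of this part, the test on clock genes and the share of higher calls among well expressed genes in the ear leaf were written before their results were seen. The other tests were chosen only after the result was seen, including the counts over other splits and the left-out libraries and spread of that share. The clock genes tested came from a wider list, built after the gene names in the files had been seen.

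The density change of the lower leaf differed from that of the ear leaf in 815 genes by the interaction test. The largest named differences were 7.70 for ICL (GRMZM2G056369), 7.06 for LIP (GRMZM2G102183), 4.61 for GH3 (GRMZM2G378106), 3.24 for CKX5 (GRMZM2G325612) and -3.44 for RADIALIS (GRMZM2G114503) on the log2 scale. The CKX5 call was lost after median-ratio rescaling and in 10 of the 12 fits without 1 library (adjusted p = 0.139 without LB replicate 3). Of 100 regroupings of the libraries within leaf positions, the real one included, 7 called at least 815 genes, with 2095 as the highest of the others, so this count does not exclude chance. All 6 other regroupings of that size kept or mirrored the real grouping of 1 leaf position, 4 the lower leaf and 2 the ear leaf. They still carry the density difference of that leaf, so the count says little about chance either way. For the upper leaf against the ear leaf, 0 genes were called, so that 100 of 100 regroupings reach the real count by construction and decide nothing. The highest of the others called 2722.

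The 6 libraries of each comparison make 10 splits into 3 and 3, too few for a share under 0.05. Only 1 of the 10, the real one, gave a count as large in each comparison. The real count and the highest other were 2953 and 0 for HE and LE, 7070 and 5 for HB and LB, 25 and 2 for HA and LA, 516 and 0 for HA and HE, 5904 and 1 for HB and HE, 1215 and 3 for LA and LE, and 61 and 1 for LB and LE.

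Photosynthesis lists were lower in HB than in LB. Normalization by the authors as the whole cause is argued against by the wider photosystem list, whose median was -1.06 after median-ratio rescaling, and LB replicate 2 by its median of -1.07 without that library (-0.92 with all). A lower share of mesophyll in the leaf pieces as the whole cause, which would raise bundle sheath transcripts, is argued against by the 5 bundle sheath markers of the wider list at a median of -0.69, although the camera call of that list was lost after median-ratio rescaling, after quantile normalization and without 4 of the 6 libraries: without any 1 library the median stayed between -0.955 (HB replicate 1) and -0.547 (HB replicate 2). The 5 mesophyll markers of the fixed list without Pep1 had a lower median, -1.394. All 5 bundle sheath markers are members of the C4 or Calvin cycle lists, so that this test partly restates the pattern. It leaves open a lower mesophyll share beside another cause. An effect of plant density on the lower leaf stays open as an untested hypothesis, as do a different sampling time or leaf age between the stands, for which no value decides. The clock-regulated gene conz1 (GRMZM2G405368) was called higher in HB than in LB and stayed called without any 1 library (limma adjusted p up to 0.0384). Its log2 fold change was then 0.523 to 0.808, above the bound of 0.5 set beforehand for the ear leaf. GI, PRR59 and gigz1b, the other clock genes given below, were not called in the lower leaf.

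More genes were higher than lower in HE against LE. A difference in library depth stays open: among genes with a mean of at least 5 RPKM 0.58 of calls were higher (0.613 to 0.66 among those genes without 1 library), above the bound set beforehand by less than the jackknife spread of 0.036. Normalization and the excess of higher calls cannot be told apart: the share was 0.62 after median-ratio rescaling but 46.2% after quantile normalization. A different sampling time of day stays open: the clock-regulated gene conz1 (GRMZM2G405368), also in the light signalling list, differed by 0.58, on either side of the bound of 0.5 set beforehand without 1 library (0.465 to 0.687; adjusted p = 0.0267, and 0.123 at most and lost without HE replicates 1 or 2 or LE replicates 1 or 3), while GI, PRR59 and gigz1b, at 0.348, 0.289 and 0.221, were not called and lay below it. Plant density stays among the open explanations, untested.

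Few genes differed between the libraries titled HA and LA, and the treatment label of LA reads high density. If the label were right, genes called the same way in both other leaves would not be expected to differ in that direction. Their median was 0.158, but 2 of 10 splits of the 6 libraries, the real one included, reached that size, up to 0.255. HA replicate 3 and LA replicate 1 correlated more with each other (0.982) than with their own groups. The LA libraries had 26271 to 27316 genes above 0 and relative depths of 0.954 to 1.084. The LE and LB libraries lay lower, at 25749 to 26187 and 0.905 to 0.943. Genes of at least 1 RPKM overlapped, with 19244 to 20090 in LA and 19174 to 19576 in LE and LB. Leaf position differs between LA and these groups too, so the library measures decide nothing. A mislabelled sample and a small density effect in the upper leaf cannot be told apart.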

How the results depend on the processing

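The wider lists, their alternatives, the lists for the interactions, the alternatives and left-out libraries of each list and named gene, the left-out libraries behind the shared density change and the upper leaf, and Pep1 left out were chosen after seeing the data; the other alternatives were planned.

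No named gene that was called reversed in sign under the alternatives tried. The excess of higher over lower calls did turn: after quantile normalization the share higher was 46.2% in HE and LE (64.3% before), 45.8% in HB and LB (66.1%) and 49.5% in HB and HE (61.8%), the last also 47.5% after median-ratio rescaling, and in LA and LE it was 46.5% after rescaling to a common sum (63.2%), with 343 higher and 474 lower without LA replicate 2. The lower-leaf interaction, 372 higher and 443 lower, turned to 1732 and 1201 without LB replicate 2, 175 and 140 without HB replicate 2, and 295 and 264 without a filter, and was near even without HE replicates 1 or 3 or LB replicates 1 or 3. HA and HE, 252 and 264, turned to 266 and 241 after median-ratio rescaling, 316 and 286 after quantile normalization, 224 and 194 without a filter, 172 and 148 with a log2 change of at least 1, 261 and 250 with limma without trend and 252 and 250 with a pseudocount of 1, and without HA replicates 1 or 3 or HE replicates 2 or 3 (118 and 75 without HA replicate 1). In HA and LA, 12 and 13, the split turned or evened out under 12 alternatives (12 and 5 without HA replicate 1). In HB and LB the median of all genes went from 0.16 to -0.01 after quantile normalization, and that of the wider nitrogen list from 0.04 to -0.08 after median-ratio rescaling and -0.217 after quantile normalization. The cause was not tested. In a tally of alternatives, 2053 values stayed. That meant counts within 1.5 times and named genes on their side of the threshold. For the shared density correlation and the upper-leaf median it meant within their jackknife spread. Another 104 values moved further, 63 of named genes no longer passed the threshold and 6 newly did. Named genes, most of the 2053, entered only with other pseudocounts, median-ratio rescaling, quantile normalization and the replicate block. Leaving out 1 or another library, not tallied for them, ended 42 of 64 named calls in HE and LE. It ended 20 of 87 in HB and LB, 12 of 77 in HB and HE and 14 of 31 in HA and HE. For LA and LE it ended 32 of 39, for LB and LE 7 of 10. The shared density correlation of 0.576 lay between 0.56 and 0.591 under other settings and between 0.535 and 0.604 without 1 library. The upper-leaf median of 0.158 was 0.343 for genes past a log2 change of 1 in both other leaves, and 0.086 to 0.237 without 1 library.

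With a log2 change of at least 1 required, counts were 920 (HE and LE), 2169 (HB and LB), 320 (HA and HE), 1692 (HB and HE) and 387 (LA and LE), fewer by construction. With only the libraries compared, HB and LB gave 4264, HA and LA 2, and LB and LE 19. Within 1.5 times, counts rose to 4168 (HE and LE), 6766 (HB and HE) and 648 (HA and HE). They fell to 977 (LA and LE) and 576 (lower-leaf interaction). In each, the spread came from fewer samples and from the compared groups alone. Why some counts rose and others fell was not tested. For HA and LA a pseudocount of 0.1 gave 13 and rescaling to a common sum 15; the replicate block gave 871 (HA and HE), 2320 (LA and LE), 195 (LB and LE), 1566 (lower-leaf interaction) and 12 (upper-leaf interaction); LA left out gave 38 for LB and LE; no filter gave 2 for the upper-leaf interaction. The cause was not tested for these. Without 1 library, counts ranged over 901 to 2514 (HE and LE), 4601 to 8973 (HB and LB), 2 to 17 (HA and LA), 158 to 818 (HA and HE), 111 to 891 (LA and LE), 23 to 89 (LB and LE), 221 to 2933 (lower-leaf interaction) and 0 to 31 (upper-leaf interaction).

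For called fixed lists, the estimated correlation gave 0 in HB and LB (4 before), HB and HE (4), LA and LE (1) and LB and LE (1). fry, which asks another question, gave 8, 9, 2 and 0. HB and LB gave 2 after median-ratio rescaling and 2 after quantile normalization, and LB and LE 0 after median-ratio rescaling. Without 1 library the ranges were 0 to 3 (HA and LA), 0 to 1 (HA and HE), 1 to 2 (LA and LE) and 0 to 2 (LB and LE). For wider lists the estimated correlation gave 0 in all 7 comparisons, and fry gave 0 in HE and LE (4 before), HA and LA (7), LA and LE (10) and LB and LE (4) and 1 in HA and HE (4). Quantile normalization gave 0 in HE and LE, 5 in HB and LB (13 before) and 3 in HA and LA; in LB and LE median-ratio rescaling gave 2 and the replicate block 7. Without 1 library the ranges were 2 to 5 (HE and LE), 9 to 14 (HB and LB), 4 to 9 (HA and LA), 1 to 12 (LA and LE) and 2 to 11 (LB and LE). The cause was not tested for these. Depth limits low values: 1 read of a rare gene stood for a median of 0.043 RPKM, and total reads are unknown.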

Other observations

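The tests on the wider lists of this part were chosen only after the data had been seen, and its single genes were picked after the result of the planned limma test was seen.

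In the lower leaf, where 7070 of 21184 genes were called, 4676 of them higher, the hormone and transcription factor lists given here did not pass camera. Of 38 genes of jasmonate and lipoxygenase metabolism, 15 were higher in HB than in LB and 2 lower (median 0.36, camera adjusted p = 0.481). Of 39 genes of abscisic acid and dehydration 11 were higher and 1 lower (median 0.25, adjusted p = 0.177). PP2C11 (GRMZM2G308615) and PP2C4 (GRMZM2G177386), protein phosphatases of the family that restrains abscisic acid signalling, rose by 1.91 and 1.58 on the log2 scale (limma adjusted p = 0.00125 and 0.000502). Of 17 AP2/ERF factors 8 were higher and 0 lower (adjusted p = 0.0753), and of 13 NAC factors 6 were higher and 0 lower (adjusted p = 0.0758). The cytokinin receptor family gene HK1 (GRMZM2G151223) rose from 3.78 ± 1.02 to 11.9 ± 3.48 RPKM (n = 3, adjusted p = 6.26e-05), CKX10 (GRMZM2G348452), which degrades cytokinins, from 9.31 ± 1.84 to 35.7 ± 8.71 (adjusted p = 0.00129). mlo1 (GRMZM2G032219), of a family that acts in mildew response, rose by 1.82 (adjusted p = 3.71e-05). PIN5a (GRMZM2G025742), of the PIN family of auxin transporters, fell by 1.94 and the potassium transporter gene HAK11 (GRMZM2G005040) by 1.89 (adjusted p = 0.000229 and 9.44e-06). In the ear leaf, 4 of 16 aquaporins were higher in HE and 1 lower (median 0.54, camera adjusted p = 0.112).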
